A study of Homo sapiens with 4 samples.

How the data were processed

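The series compared HCT116 cells, a human colorectal cancer cell line, that carried a control hairpin vector with cells in which NUDT21 was knocked down by a short hairpin RNA. NUDT21, also called CFIm25, is a subunit of cleavage factor Im, which binds UGUA motifs upstream of mRNA cleavage sites. Per the labels, there were 2 control libraries, shPLKO 1 and shPLKO 2, and 2 knockdown libraries, shNUDT21 1 and shNUDT21 5. The series description names the control shScramble. The labels do not say whether the numbers after shNUDT21 name hairpins or replicates, nor whether libraries of a group came from separate cultures. The p-values therefore measure only the spread between these libraries, which may be technical. Per the labels' protocols, libraries were made from total RNA with a SMARTer mRNA-Seq kit.

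The submitters' processing notes name Bowtie 0.12.2 and the genome build hg18, with no role or order. The counting tool, the annotation, the use of strand and the treatment of reads that match several places are not given in the sources used here. The deposited values are taken to be RPKM (reads per kilobase of gene model, scaled to the reads of the library), not logged, with 1 library per file. The file headers give no unit, so the unit was inferred from the values, and reads cannot be told from fragments. Each file held 20030 rows. In 27 of them a date stood in place of a gene symbol, and these were left out of the comparisons. Of the 20003 genes left, 2397 were at 0 in all 4 libraries.

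Depth was recovered from the values. Low genes gave the depth of each library relative to the first, and gene steps multiplied by annotated transcript lengths gave a single total for 421 transcript lengths, against 21 for the next most frequent total. The step of each gene was searched for so that its values were whole within a tolerance of 1e-06. That 100% of the values above 0 were whole numbers of reads follows from this search and is no check of it. Among genes with such a step, 0 had a gene model length that was not a whole number of bases. The totals were 30459886 and 30306821 reads for shPLKO 1 and 2 and 30243349 and 29963980 for shNUDT21 1 and 5, at most 1.66% apart. An RPKM of 1 on a gene model of 2 kb corresponds to 60.9 reads in the first library. For 1298 genes the recovered reads needed a common factor chosen from annotated lengths. The rule for that factor was revised once, because its first form put more reads on genes than the library totals. It affects the recovered reads only, not the RPKM values or the main test. Intervals from reads cover counting error only, since the reads carry no molecular identifiers.

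The main test was limma 3.58.1 in R 4.3.3, with an intensity trend, on log2(RPKM + 1) as deposited. It used all 4 libraries, no covariate, and the 11124 genes with a mean of at least 1 RPKM. It was two-sided, with Benjamini-Hochberg adjusted p under 0.05 as the threshold, 2 residual degrees of freedom and 2.71 prior degrees of freedom. Fold changes on the log2(RPKM + 1) scale understate the change of low genes, so ratios of mean RPKM are printed as well. The test had been fixed for each unit the files could hold before the data were examined.

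Also fixed before the data were examined were 26 gene lists, the other settings to be tried and the rule for the genes named in the text. That rule took NUDT21, the 10 genes with the largest positive and the 10 with the largest negative log2 fold change among those past the test with groups that did not overlap and a mean of at least 5 RPKM, and up to 4 genes with the lowest p in each list. Lists with at least 5 measured genes were tested with limma's camera at a preset correlation of 0.01, adjusted over the 23 lists tested, with camera at an estimated correlation and fry beside it. At an estimated correlation camera rests on the 2 residual degrees of freedom, so it could hardly call any list. The cholesterol list, with an estimated correlation of 0.0309, went from a camera adjusted p of 4.48e-04 to 0.852. Adjusted p-values at an estimated correlation therefore decide nothing for or against a list. GENCODE v29 was used only for symbols, transcript and 3' UTR lengths, GC content, UGUA motifs and exon overlaps of at least 50 bases. It is of another build than the one the notes name, and no coordinates are given.

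The main test was tried on 20 simulated sets of 11124 genes, drawn with the spread of each group, in which 200 genes were changed. It called 0% of the genes changed 1.5-fold, 4.9% of those changed 2-fold and 51.3% of those changed 4-fold. On average 5.4 unchanged genes were called per set, which was 13% of the calls, and 8.91% of unchanged genes had an unadjusted p under 0.05. The test was thus more permissive than its nominal level where the groups differ in spread. The simulation changed 200 genes, while 3773 genes of the data had an unadjusted p under 0.05 (limma). An adjusted threshold depends on how many genes change, so the shares called and the 13% do not carry over to the data.

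The settings chosen then were quantile normalization, no filter on low values, a pseudocount of 0.1, limma without the intensity trend, a fold threshold and leaving out each library in turn. Leaving out a library leaves a single library in its group, with the spread taken from the other group alone. The p-values and calls of those settings are therefore no measure of stability. Added after seeing the data were limma's voom on the recovered reads and the removal of a trend with GC content and gene model length from each library. Files were read and figures drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.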

Results

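Gene expression was measured by RNA sequencing in 4 libraries of HCT116 cells, 2 of control cells (shPLKO) and 2 of cells depleted of NUDT21 (shNUDT21). The recovered depth was between 29963980 and 30459886 reads per library. Between 16143 and 16336 genes were above 0 in each library. The comparison between the groups asks how NUDT21 depletion changes gene expression in these cells.

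NUDT21 was lower in both knockdown libraries. Its level was 24.3 and 26.9 RPKM in shPLKO 1 and 2, from 3266 and 3597 reads. In shNUDT21 1 and 5 it was 3.96 RPKM (95% counting interval 3.63 to 4.31) and 2.999 RPKM (2.71 to 3.31), which is 15.5% and 11.7% of the control mean. The log2 fold change was -2.58 (SE 0.16, limma adjusted p 0.0406). CPSF6, the cleavage factor Im subunit that pairs with NUDT21, rose 2.69-fold, from 9.97 ± 0.22 to 26.8 ± 2.64 RPKM (SD, n = 2 per group). It was the only 1 of the 23 other genes of the cleavage and polyadenylation machinery that passed the test over all genes. Adjusted over the list alone, 6 were higher and 2 were lower. PCF11, a factor of cleavage and transcription termination, had a ratio of 2.28 (adjusted p 0.0523), and its annotated exons overlap those of an antisense gene. CLP1 and SYMPK, which act in the same machinery, had ratios of 0.593 and 0.614 (adjusted p 0.0548 and 0.0598). The list as a whole was not called (median log2 fold change 0.15, camera adjusted p 0.274), with a median of 0.041 without shNUDT21 1 (adjusted p 0.73) and 0.304 without shNUDT21 5 (adjusted p 0.131). Without shPLKO 1 or shPLKO 2, NUDT21 had an adjusted p of 0.127 or 0.119.

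**Figure D1:**
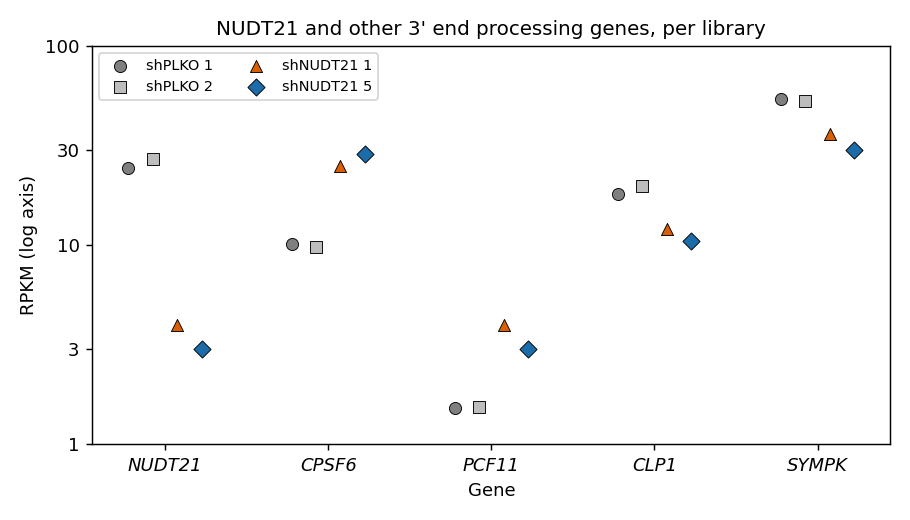
RPKM (log axis) of NUDT21 and of the 4 genes of the cleavage and polyadenylation list with the lowest p, with each library as a point. NUDT21 lies at 3.96 and 2.999 in the shNUDT21 libraries against 24.3 and 26.9 in the shPLKO libraries, and CPSF6 lies at 24.95 and 28.7 against 10.1 and 9.82.

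Across the genome, 290 genes were higher and 357 were lower in shNUDT21 (limma, 11124 genes tested). Of these, 131 and 152 changed by at least 1 on the log2 scale. Over all 11124 genes, 647 passed and 3773 had an unadjusted p under 0.05 (limma). These numbers are the background for the counts given for each list. With so many low p-values, adjustment over a list alone passes members of many lists, so such counts do not set a list apart. The highest ratio among the 10 largest increases was that of SPRR2D, a small proline-rich protein of the cornified envelope, which went from 2.60 ± 0.28 to 42.9 ± 10.3 RPKM, 16.5-fold. HMOX1, the heme oxygenase induced by oxidative stress, rose 6.67-fold to 137 ± 19.1 RPKM. SCG2, which encodes a secretory granule protein, rose 7.48-fold. UPP1, a uridine phosphorylase, rose 5.39-fold and reached 81.1 and 85.7 RPKM. LURAP1L and ARL14EPL rose 6.26-fold and 5.26-fold. SLPI, a secreted protease inhibitor, rose 4.94-fold and STC2, a secreted glycoprotein, rose 4.09-fold. CEBPD, a transcription factor, rose 3.96-fold. VCAN, the proteoglycan versican, rose 4.10-fold, to 12.1 RPKM in shNUDT21 1 and 22.5 RPKM in shNUDT21 5. SPRR2D belongs to a family of similar genes, so reads could be shared among its members.

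After NUDT21 itself, the largest decreases were those of WNT16, a secreted Wnt ligand, and LRG1, a secreted glycoprotein. WNT16 went from 33.3 ± 0.98 to 7.42 ± 3.42 RPKM, and LRG1 from 10.2 ± 0.31 to 1.77 ± 0.66 RPKM. CTGF, a matricellular protein, fell from 25.6 ± 3.46 to 6.06 ± 1.05 RPKM. The abundant keratin gene KRT8 fell from 4263 ± 178 to 1389 ± 92.2 RPKM. TMEM59L, TINAGL1, GALK1 (galactokinase) and TSPAN7 were between 3.17-fold and 3.70-fold lower. HSD11B1L went from 8.53 ± 0.17 RPKM to 2.82 RPKM in shNUDT21 1 and 1.31 RPKM in shNUDT21 5. Exons of HSD11B1L overlap those of RPL36 on the same strand, those of LRG1 and TSPAN7 overlap an unnamed gene on the same strand, and those of KRT8 and KRT18 overlap on opposite strands.

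**Figure D2:**
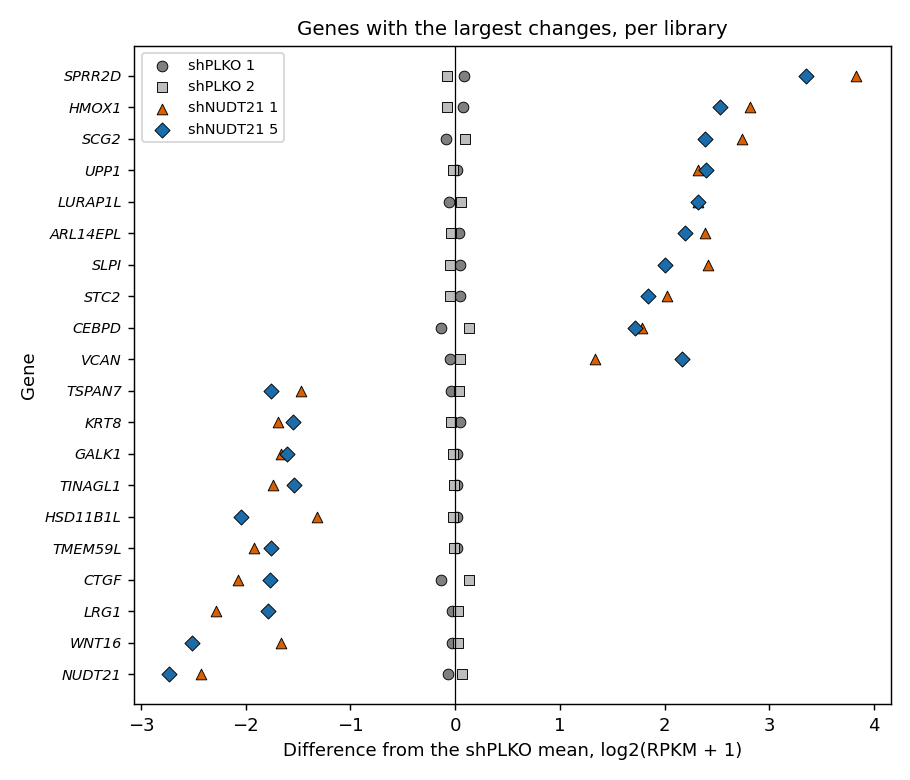
Difference of each library from the shPLKO mean on the log2(RPKM + 1) scale for the 10 genes with the largest increases and the 10 with the largest decreases, with each library as a point. The log2 fold changes run from 3.59 for SPRR2D to -2.58 for NUDT21, and the 2 groups do not overlap for any of the 20 genes, which were chosen on that condition.

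The calls lay close to the threshold, with a lowest adjusted p of 0.0406 (limma), and 3773 genes had an unadjusted p under 0.05. Without shPLKO 1 and without shPLKO 2 the same test called 1 and 0 genes (1014 and 1177 at an unadjusted p under 0.05), with no filter on low values it called 0 (4762), and with the trend of GC content and gene length removed it called 113 higher and 98 lower. After that removal, 3340 genes had an unadjusted p under 0.05 (limma). Of the genes named by the rule for named genes, 26 no longer passed, with adjusted p from 0.0501 to 0.0836. Their median log2 size went from 1.015 (median SE 0.142) to 0.862 (0.129), smaller in 22 and larger in 4, and their unadjusted p was larger in 24. They were VCAN, WNT16, HSD11B1L, CPSF6, HMGA2, GADD45A, PMAIP1, ECT2, WDR43, NKD1, XPOT, SEL1L, ENO2, ALDOA, PFKL, ALDOC, FDPS, ELOVL6, NDUFV1, ME1, TXNRD1, SNAI1, DSC2, XIAP, TNFRSF10A and CASP8. CPSF6 went from a log2 fold change of 1.339 (SE 0.134) to 0.979 (SE 0.128), and XIAP from 0.858 (SE 0.127) to 0.475 (SE 0.103). WNT16 went from -2.087 (SE 0.302) to -2.275 (SE 0.29), and its adjusted p was 0.0501 although its unadjusted p was lower.

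Genes of the ATF4 and integrated stress response stood higher as a group. Of 32 measured, 29 had a positive log2 fold change, 4 rose past the test over all genes, and 16 rose adjusted over the list alone. The 4 were STC2, PPP1R15A, XPOT and SLC7A1. PPP1R15A, a phosphatase subunit that reverses eIF2 alpha phosphorylation, went from 42.7 ± 0.30 to 141 ± 0.70 RPKM. XPOT, which exports tRNA, rose 2.44-fold, and SLC7A1, a cationic amino acid transporter, rose 2.12-fold. The list median was 0.57 (camera adjusted p 2.25e-06, adjusted p 0.852 with an estimated correlation, fry adjusted p 0.118). Among endoplasmic reticulum chaperones and unfolded protein response genes, 1 of 23 rose: SEL1L, of the degradation complex in the endoplasmic reticulum membrane, which went from 6.501 ± 0.61 to 14.6 ± 2.58 RPKM. Adjusted over the list alone it was again 1. EDEM1 and HERPUD1 had ratios of 1.77 and 1.54 and did not pass. That list's median was 0.36 (camera adjusted p 0.0421, adjusted p 0.931 with an estimated correlation, fry adjusted p 0.453). It was 0.089 without shNUDT21 1 and 0.67 without shNUDT21 5.

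In the NRF2 and glutathione list, 4 of 24 genes rose and 5 rose adjusted over the list alone, with a list median of 0.068 (camera adjusted p 0.204). The list was called higher with the GC content and gene length trend removed (median 0.144, camera adjusted p 0.0391), and with an estimated correlation its adjusted p was 0.931. The median was 0.319 without shNUDT21 5, 0.179 without shPLKO 1 and -0.024 without shNUDT21 1. Beside HMOX1, the genes were FTH1, the ferritin heavy chain, from 2307 ± 54.9 to 6185 ± 429 RPKM, ME1, malic enzyme, 2.06-fold, and TXNRD1, thioredoxin reductase, 2.03-fold. FTH1 has processed pseudogenes, and reads could be shared with them.

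Genes of sterol and fatty acid synthesis and of the respiratory chain were lower as groups. Of 33 genes of cholesterol and fatty acid synthesis, 27 had a negative log2 fold change, 3 fell, 1 rose, and 12 fell and 1 rose adjusted over the list alone. IDI1, FDFT1 and FDPS, enzymes of the mevalonate and sterol pathway, fell to 0.387, 0.432 and 0.483 of their control means. FDFT1 went from 65.9 ± 0.42 to 28.5 ± 3.24 RPKM. The gene that rose was ELOVL6, a fatty acid elongase, from 4.05 ± 0.15 to 8.75 ± 0.0036 RPKM. The list median was -0.34 (camera adjusted p 4.48e-04, adjusted p 0.852 with an estimated correlation, fry adjusted p 0.0953). Among nuclear genes of the respiratory chain, 35 of 41 had a negative log2 fold change and 1 fell over all genes tested, NDUFV1 of complex I, from 123 ± 5.66 to 66.0 ± 5.34 RPKM. Adjusted over the list alone, 3 fell. ATP5F1D, SDHA and COX6B1 had ratios of 0.581, 0.631 and 0.612 and did not pass over all genes. The list median was -0.41 (camera adjusted p 1.54e-04, adjusted p 0.852 with an estimated correlation, fry adjusted p 0.107) and -0.254 without shNUDT21 5. It was -0.244 with the GC content and gene length trend removed, where the call held. Of 34 hypoxia and glycolysis genes, 5 fell, and 10 fell and 4 rose adjusted over the list alone. ENO2, ALDOA, PFKL and ALDOC, all of glycolysis, stood at 0.428, 0.535, 0.548 and 0.447 of control. That list was not called (median -0.12, camera adjusted p 0.119). Its median was -0.12 without shNUDT21 5 and -0.247 without shNUDT21 1, and its camera adjusted p was 0.852 with an estimated correlation.

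Genes of G2/M and mitosis stood higher in the group mean, with a large difference between the knockdown libraries. Of 36 G2/M and mitosis genes, 33 had a positive log2 fold change and 1 rose, over all genes and adjusted over the list alone: ECT2, an exchange factor of cytokinesis, from 2.84 ± 0.44 to 6.78 ± 0.65 RPKM. TTK and NDC80, of the spindle checkpoint and kinetochore, had ratios of 2.29 and 2.57 and did not pass, with NDC80 at 12.97 RPKM in shNUDT21 1 and 7.31 RPKM in shNUDT21 5. The list median was 0.49 (camera adjusted p 3.16e-04, adjusted p 0.931 with an estimated correlation, fry adjusted p 0.441). Without shNUDT21 1 it was 0.045, and without shNUDT21 5 it was 0.898. In the G1/S and replication list, 0 of 38 genes passed over all genes or adjusted over the list alone (limma, 7 at an unadjusted p under 0.05, 0 called with voom, median 0.19, camera adjusted p 0.175). The median was -0.134 without shNUDT21 1, 0.645 without shNUDT21 5 and 0.230 without shPLKO 1, and with an estimated correlation the camera adjusted p was 0.939. MCM2, a helicase subunit, had a ratio of 0.593 against 1.65 for RRM1, of ribonucleotide reductase. Of 12 measured replication-dependent histone genes, 0 passed either way (limma, 6 at an unadjusted p under 0.05, 0 called with voom) and 10 had a positive log2 fold change. Most mRNAs of such genes lack a poly(A) tail, and the values do not tell tailed transcripts from untailed ones. Under the level filter were 29 of the 41 histone genes listed. HIST1H1C went from 131 ± 4.89 to 238 ± 62.2 RPKM without passing. The histone median was 0.50 (camera adjusted p 0.0497, adjusted p 0.912 with an estimated correlation, fry adjusted p 0.239) and 0.144 without shNUDT21 1. These genes form families of similar sequence, so their reads could be shared.

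The genes of the p53 and cell death lists that passed the test rose. Over all genes, 647 of the 11124 tested passed. Of 30 p53 targets, 2 rose over all genes and adjusted over the list alone: GADD45A, from 145 ± 7.51 to 279 ± 19.9 RPKM, and PMAIP1, which encodes the cell death factor NOXA, from 45.8 ± 0.51 to 145 ± 49.9 RPKM. MDM2, the p53 ubiquitin ligase, had a ratio of 2.32 (20.6 and 12.8 RPKM in shNUDT21 1 and 5) and did not pass. The list median was -0.026, its mean was 0.005, and it was not called (camera adjusted p 0.966). Its median was -0.245 without shNUDT21 1 (adjusted p 0.315) and 0.074 without shNUDT21 5 (adjusted p 0.156). Of 30 apoptosis regulators, 4 rose, and the same number adjusted over the list alone. They were PMAIP1, XIAP, an inhibitor of caspases, at 1.99-fold, TNFRSF10A, a death receptor for TRAIL, at 1.95-fold, and CASP8, its initiator caspase, at 1.79-fold. The list was not called by camera (median 0.021, adjusted p 0.304), and its median ran from -0.003 without shPLKO 2 (adjusted p 0.282) to 0.157 without shNUDT21 5 (adjusted p 0.192). In fry, which asks whether a list's own genes move on balance to a side, it had an adjusted p of 0.0023. It was the only list that fry called, and none of the lists called by camera passed fry.

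Interferon and inflammatory genes were higher as groups at the edge of the threshold in camera at the preset correlation. Fry called neither list (adjusted p 0.208 and 0.103). Of 26 interferon-stimulated genes, 1 rose, over all genes and adjusted over the list alone: IRF1, a transcription factor, from 5.13 ± 0.17 to 9.56 ± 0.20 RPKM. IFI27 had 3.93 and 3.07 RPKM in the controls and 10.9 and 34.0 RPKM in shNUDT21 1 and 5, and IFIH1, a sensor of double-stranded RNA, had a ratio of 3.83 (2.91 and 5.67 RPKM in shNUDT21 1 and 5). Neither passed. The list median was 0.38 (camera adjusted p 0.0497, adjusted p 0.912 with an estimated correlation) and 0.217 without shNUDT21 5 (adjusted p 0.574). Of 14 NF-kappa-B and inflammatory genes, NFKB1 rose 2.04-fold, and 3 rose adjusted over the list alone, among them the chemokine genes CXCL8 and CXCL1. That median was 0.28 (camera adjusted p 0.0497, adjusted p 0.852 with an estimated correlation), 0.177 without shNUDT21 5 (adjusted p 0.192) and 0.405 without shNUDT21 1 (adjusted p 0.0768). It was also not called without shPLKO 2, with no filter, with a pseudocount of 0.1, without the intensity trend or with voom, and without the intensity trend or with voom the interferon and histone calls were lost too.

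Epithelial genes went in opposite directions. Of 33 adhesion and junction genes, 4 rose and 2 fell, and 5 rose and 2 fell adjusted over the list alone. ESRP1, an epithelial splicing regulator, went from 22.7 ± 1.13 to 67.7 ± 7.79 RPKM. DSC2, a desmosomal cadherin, rose 2.87-fold. The other 2 that rose, DSG2 and OCLN, were named after their values were seen, since the rule for named genes left them out. They rose 1.93-fold and 2.02-fold (log2 fold change 0.926 and 0.869), and with the GC content and gene length trend removed they did not pass (0.642 and 0.523, adjusted p 0.0657 and 0.0757). KRT8 and its partner KRT18 fell to 0.326 and 0.329 of control. Both keratins have processed pseudogenes. Of 17 mesenchymal genes, CTGF and SNAI1 fell, and 4 fell and 2 rose adjusted over the list alone. SNAI1, a transcription factor of the epithelial to mesenchymal transition, stood at 0.558 of control. This list had a median of 0.044 and a mean of -0.067 (camera direction lower), and its median was 0.158 without shNUDT21 1 (adjusted p 0.373) and -0.063 without shNUDT21 5 (adjusted p 0.115). Of 16 Wnt and beta-catenin targets, NKD1, a feedback inhibitor of Wnt signalling, fell to 0.475 of control, and 5 fell and 1 rose adjusted over the list alone. Of 5 measured genes of intestinal differentiation, 0 passed over all genes (limma, 4 at an unadjusted p under 0.05, 0 called with voom), and 2 rose and 2 fell adjusted over the list alone. HNF4A had a ratio of 1.57 and KRT20 a ratio of 0.627. Camera called none of these 4 lists (adjusted p 0.256, 0.725, 0.119 and 0.637). The adhesion and junction list, with a median of 0.243, was called higher with the GC content and gene length trend removed (0.291, camera adjusted p 0.0494). It was at 0.377 without shNUDT21 1 and at 0.046 without shNUDT21 5. With an estimated correlation its adjusted p was 0.931. The Wnt list had a median of -0.215, and -0.365 without shNUDT21 1 (adjusted p 0.236). The differentiation list had a median of 0.379, with 0.221 without shNUDT21 5. With no filter on low values it was -0.013 over 25 genes (camera adjusted p 0.929).

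Among the remaining lists, 1 of 40 splicing genes fell, also adjusted over the list alone: SNRNP70, of the U1 particle, from 184 ± 0.40 to 83.7 ± 0.55 RPKM. Of 29 genes of ribosome biogenesis, WDR43 rose 1.70-fold, and 3 rose and 2 fell adjusted over the list alone. Of 26 chromatin repressors and of 58 cytosolic ribosomal proteins, 0 passed over all genes or adjusted over the list alone (limma, 6 and 1 at an unadjusted p under 0.05, 0 and 0 called with voom). EZH2, a histone methyltransferase, had a ratio of 2.04 and RPL18 a ratio of 0.722. Of 20 genes that earlier work on other cells named for altered 3' UTR use after NUDT21 loss, HMGA2, a chromatin architectural factor, rose from 10.6 ± 1.33 to 37.3 ± 9.02 RPKM, and 2 rose adjusted over the list alone, the other being PAK2, a kinase, with a ratio of 1.91. Camera called none of these 5 lists (adjusted p 0.725, 0.637, 0.396, 0.119 and 0.396). Without shNUDT21 1 the splicing, ribosomal protein and ribosome biogenesis lists had medians of -0.281, -0.334 and -0.184. Without shNUDT21 5 they were at 0.161, 0.103 and 0.29. With an estimated correlation the adjusted p of these 3 lists was 0.972, 0.939 and 0.972. The chromatin list had a median of 0.072, with -0.034 without shNUDT21 1 (adjusted p 0.71) and 0.231 without shNUDT21 5 (adjusted p 0.0566). The list from earlier work had a median of 0.11, and 0.063 without shPLKO 1 (adjusted p 0.484). Markers of other cells were sparse, with 17 of 18 fibroblast and endothelial genes and 17 of 17 leukocyte genes under the level filter. The fibroblast gene measured, COL1A1, had 6.53 ± 0.27 RPKM in shPLKO and 5.67 ± 1.83 RPKM in shNUDT21 and did not pass. Of 3 measured markers of HEK293-type cells, TUBB3 fell to 0.472 of control, from 121 ± 5.58 RPKM, while GAL had a ratio of 1.45 and PAX2 a ratio of 1.24 (2.16 and 1.14 RPKM in shNUDT21 1 and 5) and neither passed.

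The knockdown libraries shared much of their change and differed in the rest. Across the 11124 genes, the change of shNUDT21 1 against a control correlated with that of shNUDT21 5 against the other control at r = 0.635 and 0.577 for the 2 ways of assigning controls, with covariances of 0.186 and 0.174. Genes are not independent replicates. The root mean square SD between libraries was 0.089 on the log2 scale for shPLKO and 0.333 for shNUDT21. At least 2-fold differences separated the shPLKO libraries at 5 genes and the shNUDT21 libraries at 452. The first principal component held 67.4% of the variance and separated the groups, and the second held 30.5% and separated shNUDT21 1 from shNUDT21 5. The groups did not overlap at 66.2% of genes, against 39.4% of unchanged genes simulated with the spread of each group.

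**Figure D3:**
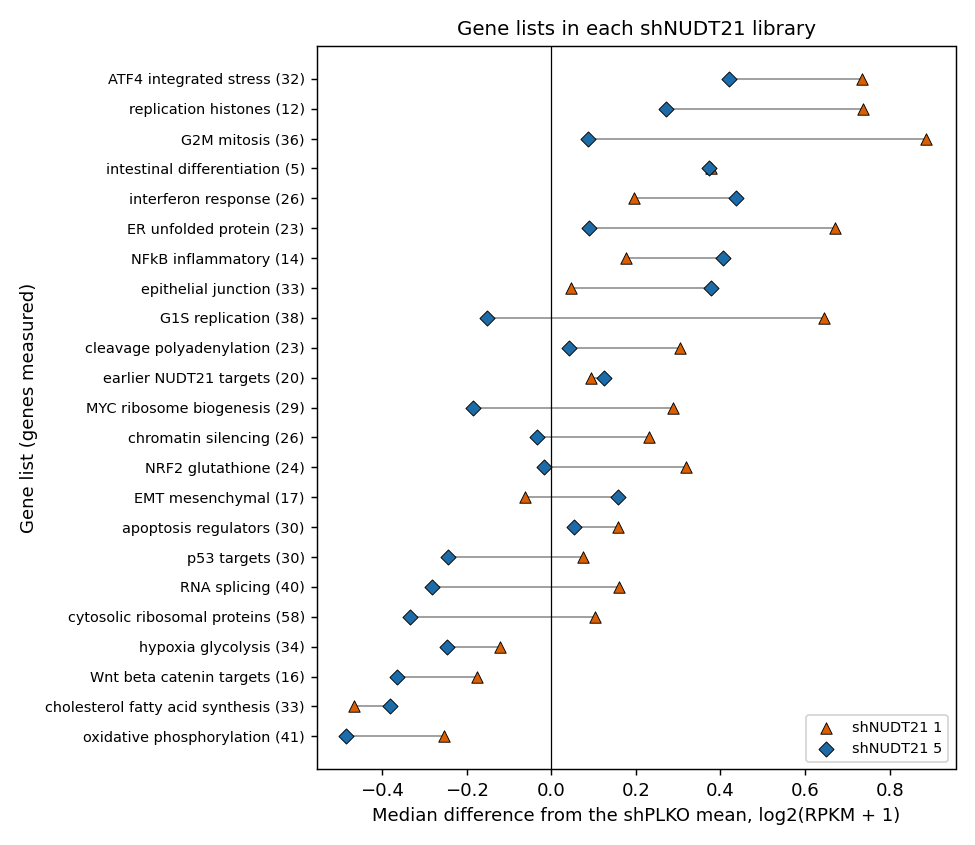
Median difference from the shPLKO mean on the log2(RPKM + 1) scale over each of the 23 gene lists, with a triangle for shNUDT21 1, a diamond for shNUDT21 5 and the number of genes measured in brackets. The ATF4 list lies at 0.735 and 0.42 and the cholesterol list at -0.467 and -0.38, while the G2/M list lies at 0.887 and 0.088.

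NUDT21 acts on the choice of 3' ends, so the change was set against annotated 3' UTR length in 11056 genes (99.4% of those tested). Genes in the fifth with the longest 3' UTRs (median 4366 bases) had a median log2 fold change of 0.13, and those in the fifth with the shortest (median 257 bases) had -0.16. Spearman's rho across genes was 0.212. The same rho was 0.338 between the 2 control libraries, shPLKO 2 against shPLKO 1, where the genes with the longest and the shortest 3' UTRs had medians of 0.076 and -0.036. It was 0.118 for shNUDT21 5 against shNUDT21 1. The values are sums over gene models, so they do not show which 3' end a transcript used.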

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

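Of the 27 rows in which a date stood in place of a gene symbol, 19 reached the level filter, and 1 passed limma's test when these rows were added to the genes tested. It had 9.60 and 10.0 RPKM in shPLKO 1 and 2 and 4.21 and 2.58 RPKM in shNUDT21 1 and 5, a log2 fold change of -1.32 (SE 0.21, limma adjusted p 0.0457). It drew attention because it lies outside the comparisons of the report, since its gene was not identified from the date. At an unadjusted p under 0.05, 6 of the 19 rows differed. No explanation of this difference was tested.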

How the results depend on the processing

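Voom and the removal of the GC content and gene length trend were added after seeing the data. The cause of a difference was not tested except where stated. With no filter on low values 17606 genes were tested and 0 were called in each direction (limma, 4762 at an unadjusted p under 0.05), and NUDT21 had a log2 fold change of -2.578 (adjusted p 0.0653). With the GC and length trend removed, 113 genes were higher and 98 lower (limma, 3340 at an unadjusted p under 0.05), and 204 of the 647 main calls were kept. A log2 fold change of at least 1 left 131 higher and 152 lower. Leaving out each library gave from 0 to 3737 genes higher and from 0 to 4021 lower, a NUDT21 change from -2.734 to -2.423, from 3 to 8 lists higher and from 2 to 4 lower. Without shPLKO 1 (1 higher, 0 lower, NUDT21 adjusted p 0.127) or shPLKO 2 (0 and 0, adjusted p 0.119) the spread comes from the shNUDT21 libraries alone, with 1 residual degree of freedom, and the lone control is assumed to vary as they do. Without shNUDT21 1 (3606 higher, 4021 lower) or shNUDT21 5 (3737 and 3535) it comes from the controls, and the lone library is assumed to vary as they do, so these counts are no measure of stability. Among gene lists (6 higher, 2 lower by camera), 3 were higher without the intensity trend, 3 with voom and 3 without shNUDT21 1, where 4 were lower. With an estimated correlation, where camera rests on 2 residual degrees of freedom and could hardly call a list, 0 were higher and 0 lower. With fry 1 was higher and 0 were lower. Of the 23 lists and the 111 genes named by the rule, 0 were called in opposite directions in 2 settings. The rule favoured genes that moved the same way in both knockdown libraries, so for genes this count is no measure of stability. Outside the rule, NQO1, GDF15, SEMA7A, DHRS2 and CD59 changed in opposite directions without shNUDT21 1 and without shNUDT21 5. Over these settings the NUDT21 adjusted p ran from 8.95e-175 to 0.127. The mean correlation of the shNUDT21 libraries was 0.606 and 0.575 at a mean of at least 10 RPKM, and the rho with 3' UTR length was 0.212 and 0.216. Quantile normalization (312 higher, 426 lower), a pseudocount of 0.1 (277 and 311), no trend (271 and 336) and voom (362 and 382) kept between 584 and 611 of the main calls. No paired analysis was possible because the groups share only the number 1.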

Other observations

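The 2 knockdown libraries differed by gene group, a comparison of single libraries with no replicate check, made after seeing the data. Of 38 G1/S and replication genes, 36 were higher in shNUDT21 1 than in shNUDT21 5, with a median log2 difference (5 minus 1) of -0.853, which lies at percentile 0 among 10000 random lists matched on level. Genes of a shared function can move together, which random lists leave out. The percentiles therefore rank the lists and do not measure chance. All 36 G2/M genes (-0.769) and all 23 unfolded protein response genes (-0.59) were higher in shNUDT21 1, both at percentile 0, as were 58 of 58 cytosolic ribosomal proteins (-0.393). Random lists matched to the ribosomal proteins also leaned to shNUDT21 1, mostly between -0.292 and -0.017. The ribosome biogenesis (-0.491), ATF4 (-0.38), splicing (-0.379) and p53 (-0.345) lists also lay at percentile 0. Mesenchymal genes (0.386), interferon genes (0.31) and epithelial genes (0.219) leaned to shNUDT21 5, at percentiles 100, 100 and 99.8. The genes with the largest differences at a mean of at least 5 RPKM, chosen after their values were seen, included DHRS2 (33.2 in shNUDT21 1, 3.94 RPKM in shNUDT21 5), GDF15 (567 and 128) and NQO1 (297 and 72.0), and in the other direction SEMA7A (31.9 and 267), MXD1 (5.13 and 40.3) and CD59 (28.7 and 141). NQO1, a classical NRF2 target, stood at 134 and 129 RPKM in the controls, above shNUDT21 5 and below shNUDT21 1.

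The tests below on the calls and their fold sizes, on slopes with 3' UTR length and UGUA density, on the trend between the knockdown libraries, and on genes moving opposite ways were chosen after the result was seen. The other tests were written before their own values were seen, but after simple correlations of the change with GC content and length had been.

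The first pattern is the set of genes called, set against a trend with GC content and gene length. GC content went with the change at rho -0.391 across genes, and with the difference between the control libraries at -0.485. The first criterion was whether at least 50% of the calls were kept after removal of the trend: 31.5% were, so by it the trend is a candidate cause. The calls lay close to the threshold, and with no filter on low values 0 were made. After the removal 3340 genes had an unadjusted p under 0.05 (limma), against 3773 before. The number of calls therefore decides little about the trend. A second criterion, chosen after that outcome, was fold size. The median size of the called changes went from 0.966 (median SE 0.131) to 0.842 (0.117), with 646 of 646 in the same direction. The named genes that lost their call ended at limma adjusted p from 0.0501 to 0.0836. The trend thus made up the smaller part of the median fold. These genes were picked from the same data for large changes, and the trend held 15.9% of the variance over all genes. A loss of most of the fold was therefore unlikely from the start, and this criterion decides little about cause. The ATF4, cholesterol, respiratory chain and G2/M list medians were 0.677, -0.358, -0.244 and 0.391 after removal, all still called by camera at the preset correlation, which argues against the trend as their whole cause. Without the removal, these lists had a camera adjusted p of 0.852, 0.852, 0.852 and 0.931 at an estimated correlation. That setting rests on 2 residual degrees of freedom and decides nothing here. The G2/M median fell to 0.045 without shNUDT21 1.

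The second pattern is the difference between shNUDT21 1 and shNUDT21 5. The GC and length trend accounts for 2.7% of the variance of the difference, which argues against it as the main cause. Unequal knockdown was tested first by the slope of the change in shNUDT21 5 on that in shNUDT21 1 over 646 called genes, which was 0.989 (95% interval over resampled genes 0.969 to 1.01), an interval that includes 1 and decides nothing. A second test, chosen after that outcome with limits set at the same time, used the 7528 genes with a mean of at least 5 RPKM. It found 22 at least 1.5-fold above both controls in 1 knockdown library and at least 1.5-fold below both in the other. Another 743 moved the same way. A graded response to the NUDT21 level would move a gene the same way in both knockdown libraries. The 22 genes were picked for moving opposite ways, and each side rests on a single library. No count expected from the spread between libraries was computed. The second test therefore cannot decide, and unequal knockdown stays open. Different hairpins, separate cultures and growth state stay open, since the labels do not tell them apart.

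The third pattern is the higher level of genes with long 3' UTRs. A hypothesis is that 3' UTR length itself, or UGUA motifs that cleavage factor Im binds, may mark the genes that change. With GC content and gene model length taken out, rho with 3' UTR length was -0.005, against 0.009 between the controls. The log2 change per doubling of 3' UTR length went from 0.0572 to 0.00212 (95% interval across genes -0.00457 to 0.0088). For the group mean, this argues against a large effect of annotated 3' UTR length beyond GC content and gene model length. The slope was -0.00396 (-0.0112 to 0.00333) in shNUDT21 1 and 0.00819 (0.000441 to 0.0159) in shNUDT21 5. Between the controls it was 0.00114 (-0.000452 to 0.00274). The knockdown libraries differ, so a small relation in shNUDT21 5 stays open. The gene model holds the 3' UTR, so an effect shared with its length cannot be told apart. With 3' UTR length also taken out, rho with UGUA density was 0.035, against 0.056 between the controls. The criterion written beforehand, a rho above that of the controls, could not exclude UGUA density, because rho has no scale and the variance was 0.239 for the change and 0.0156 between the controls. The log2 change per motif per kb was 0.00339 (0.000722 to 0.00606), against 0.00128 (0.000645 to 0.00192) between the controls. It was 0.00604 (0.00314 to 0.00895) in shNUDT21 1, above the control interval, and 0.000733 (-0.00236 to 0.00383) in shNUDT21 5. The intervals of the group mean and of shNUDT21 5 overlap that of the controls. The 2 knockdown libraries differ, so a small relation to UGUA density stays open. A shift in 3' end use was not measured.

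Under the level filter, 19 genes had 0 reads in both controls and at least 3 reads in both knockdown libraries, and 24 had the opposite.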
